A study of Homo sapiens with 6 samples.

How the data were processed

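Poly-A RNA was sequenced from ABL cells, a castration-resistant metastatic prostate cancer line kept in hormone-depleted serum. The cells had been treated for 72 h with 100 µM UK5099 (3 libraries) or with vehicle (3 libraries). UK5099 is an inhibitor of the mitochondrial pyruvate carrier, which brings pyruvate from the cytosol into mitochondria. Per the labels' protocols, the treatments were done in biological triplicate in dishes, and libraries were made with a stranded kit. All 6 libraries are of the same cell line, so the p-values describe the spread between cultures of that line.

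Reads were aligned with TopHat2 2.0 to hg19 and quantified with Cufflinks 2.0, per the submitters' processing notes. The annotation release and the strand setting of the quantification are not given in the sources used here. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of a library) in a table of 59977 lines, each with an Ensembl gene ID and a symbol. The values had been quantile normalized across the 6 libraries, which was seen from the values and is not stated in the labels. Of the 13519 highest ranks, 99.4% held values equal within a relative tolerance of 0.001 in all 6 libraries, and the FPKM sums of the libraries differed by 0.00291%. Quantile normalization gives every library the same distribution, so a shift of the whole transcriptome cannot be seen, and the highest values move in steps from rank to rank. The values hold no counts, so the depth of each library is unknown. No count model was used and no counting interval was computed.

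The 28 symbols that a spreadsheet had turned into dates were restored from their gene IDs. Of all gene IDs, 56527 (94.2%) were found in GENCODE 29, which was used for gene types, transcript length and GC content. That annotation is of another genome build than the deposited values, so no coordinates are given. Symbols are those of the deposited table. TXNIP, a gene chosen in advance, is not analysed here.

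Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Fold changes are on this scale, which understates the change of genes with low FPKM. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested. A symbol on several lines was represented by the line with the highest mean. This left 13490 genes. A linear model with the treatment as its only term was fitted per gene, with moderated variances that followed the mean (eBayes with a trend). Two-sided p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The design, the 27 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where another time is given. The 23 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with a correlation estimated from the data was run beside it, as was fry, which tests a list against no change and not against other genes. With an estimated correlation, camera takes its degrees of freedom (independent pieces of information) from the libraries, not from the number of genes. Fewer degrees of freedom give a higher p for the same difference, whatever the correlation. Ranges of list p-values are of camera alone. Counts of changed members are also given adjusted over the list alone.

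Genes were named by a fixed rule. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose treated and vehicle libraries did not overlap. It took up to 4 members past the threshold with the smallest p in each list, and 10 genes chosen in advance, among them MPC1, MPC2, KLK3, ATF4, DDIT3, CDKN1A, TXNIP and LDHA. Some genes that the rule takes are not reported here. Other list members named in the text, to show what a small count is made of, were chosen after their values were seen. Means are given with the SD over 3 libraries, and log2 fold changes with their SE.

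The labels give both groups the replicate numbers 1 to 3 without saying what a number stands for. Deviations from the group means over all tested genes correlated between same-numbered libraries at 0.14, 0.229 and 0.169, and between differently numbered ones at no more than 0.03. The deviations within a group cancel out for each gene, so high values for some pairs force low ones for others. The low values are therefore not separate evidence of pairing. By the rule set in advance (each pair over 0.1) the numbers were taken to pair the libraries, though 3 pairs are too few to establish it. A fit with the replicate number as a block was run beside the main one, and its value is given for each named gene whose call it changed and each count it moved by over 1.5 times.

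The alternatives were other pseudocounts (0.1 and 0.5), no filter and a stricter filter (5 FPKM), and further quantile, trimmed-mean (TMM, unweighted) and median scaling. Robust and untrended variance models, the replicate block, summed lines per symbol, each library left out in turn, a 1.5-fold threshold and a threshold of 0.01 were also run. Ranking the values again without MT-RNR2 and removing loess trends over GC content and transcript length were added after the data had been seen, as were 6 further gene lists. A test for raw counts had been planned in case the table held counts and was not run. The procedure was tested on simulated values with the means and spreads of these 13490 genes, 200 of them changed. It recovered 10% of changes of 0.25 log2 units, 34% of 0.5, 90% of 1 and 100% of 2, with 4 calls among unchanged genes. Many more genes (3775) were called in the data than were changed here, so these shares need not hold for the data. The list test called a simulated list of 20 genes shifted by 0.5 and none of 99 unshifted lists. The simulated genes varied independently of each other, so this does not measure false calls in lists whose genes vary together.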

Results

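The transcriptome of ABL prostate cancer cells was measured after 72 h with 100 µM UK5099 or vehicle, with 3 libraries in each group. The comparison asks which transcripts change when the mitochondrial pyruvate carrier is inhibited in castration-resistant cells. The deposited FPKM values had been quantile normalized, with sums of 658703 to 658722 per library, and the sequencing depth is unknown. The libraries separated by treatment: correlations over genes were 0.982 to 0.991 within groups and 0.969 to 0.975 between them. The first principal component held 52.5% of the variance. Both measures include MT-RNR2, which was listed at 0 in all 3 UK5099 libraries and at 22878 FPKM in all 3 vehicle libraries. That gene adds to the difference between groups by an amount that was not computed.

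UK5099-treated cells had higher levels of stress and amino acid genes and lower levels of glycolysis and DNA replication genes. With an estimated correlation, and thus fewer degrees of freedom, the ATF4 and replication lists passed camera (adjusted p = 0.0141 for each). The glycolysis list did not (adjusted p = 0.130), though it passed camera with the preset correlation (adjusted p = 6.00e-11). On the log2(FPKM + 1) scale, the largest rise past the threshold was that of CHAC1, a glutathione-degrading enzyme induced by ATF4, from 2.59 ± 0.0764 to 49.4 ± 3.63 FPKM (SD, n = 3), a log2 fold change of 3.81 ± 0.07 (SE; adjusted p = 9.66e-08). PFKFB3, an activator of glycolysis, fell from 8.43 ± 0.895 to 1.97 ± 0.329 FPKM (log2 fold change −1.67 ± 0.11, adjusted p = 6.45e-05). Of 13490 genes tested with limma, 1728 were higher and 2047 lower with UK5099 at an adjusted p of 0.05. Most changes were small: 433 of the higher and 305 of the lower genes changed at least 1.5-fold, and 133 and 29 at least 2-fold. The treated and vehicle libraries did not overlap for 3771 of the 3775 called genes, and for 45.0% of all tested genes, where chance gives 10%. Without UK5099 replicate 1, 1093 genes were higher and 1298 lower. At an adjusted p of 0.01, 846 were higher and 926 lower.

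Of the 12 largest rises, 9 belonged to the list of ATF4 and amino acid response genes: CHAC1, GDF15, SESN2, DDIT3, TRIB3, SLC6A9, DDIT4, SLC7A11 and PCK2. GDF15, a secreted stress cytokine, rose by 2.85 ± 0.10 on the log2 scale, and SESN2, which restrains mTORC1 signalling, by 2.65 ± 0.08. Outside that list were FAM129A (2.46 ± 0.07), the peptide hormone gene ADM2 (2.34 ± 0.08) and RP11-348H3.4. RP11-348H3.4, a processed pseudogene, was listed at 0 in 2 vehicle libraries and at 0.779 FPKM in the other, against 5.13, 7.74 and 11.03 with UK5099; reads shared with its parent gene leave its value uncertain.

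The 12 largest falls included PFKFB3, the fucosyltransferase gene FUT11 (−1.55 ± 0.08), LDHA (−1.53 ± 0.06), FAM111B (−1.30 ± 0.09), the transcription factor gene MYB (−1.28 ± 0.07) and the apelin gene APLN (−1.28 ± 0.10). COLCA1, a transcript antisense to another gene, fell by 1.31 ± 0.09, and the non-coding RP11-319F12.2 fell by 1.71 ± 0.16. The other falls were RP11-598P20.5, the processed pseudogene CTC-535M15.1, the short RNA model HOXA11-AS1_4 and MT-RNR2. Values of antisense and pseudogene transcripts are uncertain, since the strand setting and the treatment of shared reads are not given in the sources used here. MT-RNR2, the large mitochondrial ribosomal RNA, was listed at 0 in all 3 UK5099 libraries and at 22878 FPKM in all 3 vehicle libraries, so no fold is given. RP11-927P21.12 was the other called gene listed at 0 throughout a group, the vehicle group.

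All 34 tested members of the ATF4 and amino acid response list rose with UK5099, and none fell (34 adjusted over the list alone). The list holds targets of ATF4, the transcription factor of the integrated stress response. ATF4 itself (ENSG00000128272.14) rose from 261 ± 6.50 to 722 ± 22.9 FPKM (log2 fold change 1.47 ± 0.04, adjusted p = 4.89e-07). DDIT3, which encodes the stress factor CHOP, rose from 28.4 ± 0.197 to 179 ± 2.95 FPKM (2.61 ± 0.04, adjusted p = 7.35e-08). ASNS, which makes asparagine, rose from 60.2 ± 1.08 to 259 ± 1.83 FPKM (2.09 ± 0.04), and DDIT4 rose by 2.40 ± 0.06. The median log2 fold change of the list was 1.47, and the list stood above all other genes by camera (adjusted p = 1.695e-39; adjusted p = 0.0141 with an estimated correlation).

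**Figure D1:**
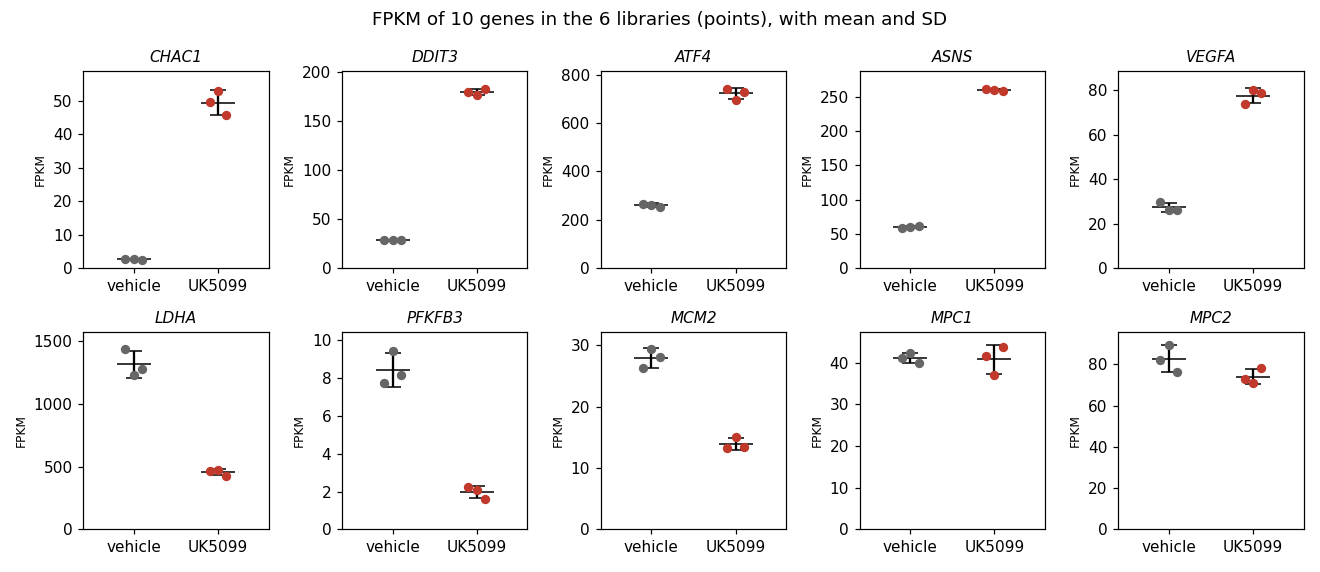
FPKM (vertical axes, linear from 0) of 10 genes in the 3 vehicle and the 3 UK5099 libraries (points), with the mean (horizontal line) and SD (error bars). CHAC1, DDIT3, ATF4, ASNS and VEGFA were higher in every UK5099 library, LDHA, PFKFB3 and MCM2 were lower, and the groups overlapped for MPC1 and MPC2.

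Of 20 tested genes of the endoplasmic reticulum stress response, 14 rose and none fell (16 adjusted over the list alone). XBP1, a transcription factor of this response, rose from 94.0 ± 3.64 to 219 ± 3.29 FPKM (1.21 ± 0.04, adjusted p = 2.73e-06). HERPUD1 rose by 1.08 ± 0.04, SEL1L by 0.86 ± 0.06 and the chaperone gene HSPA5 by 0.63 ± 0.04. Of the 12 chaperones and folding enzymes in the list 6 rose. The 6 members of the list that did not pass were all of this kind. Among them were HSP90B1 (0.15 ± 0.07, adjusted p = 0.162) and PDIA4 (0.08 ± 0.05, adjusted p = 0.219). With the replicate block HSP90B1 was past the threshold (adjusted p = 0.0175). The list test gave an adjusted p of 6.00e-11 (adjusted p = 0.0210 with an estimated correlation).

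The targets of the drug themselves showed no change past the threshold. MPC1 (ENSG00000060762.18) was at 40.8 ± 3.46 FPKM with UK5099 and 41.0 ± 1.15 with vehicle (log2 fold change −0.01, 95% interval −0.17 to 0.15, adjusted p = 0.932). MPC2 (ENSG00000143158.10) was at 74.0 ± 3.76 and 82.6 ± 6.52 FPKM (−0.16, interval −0.32 to 0.0045, adjusted p = 0.132). Among 21 tested genes of pyruvate metabolism, 4 rose and 6 fell, the same counts as adjusted over the list alone. PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate, rose from 26.3 ± 2.05 to 124 ± 9.12 FPKM (2.20 ± 0.08), and malic enzyme ME1 rose by 0.93 ± 0.07. LDHA (ENSG00000134333.13), which interconverts pyruvate and lactate, fell from 1311 ± 106 to 454 ± 23.2 FPKM (−1.53 ± 0.06, adjusted p = 4.89e-06). The pyruvate list was not past the threshold (adjusted p = 0.512), and its median of −0.06 and mean of 0.06 differed in sign.

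Glycolysis genes fell together: 16 of 20 tested members were lower and none higher (18 lower adjusted over the list alone), with a median log2 fold change of −0.48. Besides LDHA and PFKFB3, PKM fell from 541 ± 17.8 to 333 ± 12.6 FPKM (−0.70 ± 0.04) and ENO1 from 502 ± 11.9 to 324 ± 16.4 FPKM (−0.63 ± 0.04). The list test gave an adjusted p of 6.00e-11, which did not hold with an estimated correlation (adjusted p = 0.130). Of 17 hypoxia response genes, 11 fell and 2 rose, the same counts as adjusted over the list alone. P4HA1 (−0.96 ± 0.06), BNIP3 (−0.93 ± 0.08) and NDRG1 (−1.08 ± 0.09) fell. VEGFA, the angiogenic growth factor, went the other way, from 27.3 ± 1.99 to 77.5 ± 3.35 FPKM (1.48 ± 0.07, adjusted p = 9.72e-06), and P4HA2 rose by 0.60 ± 0.07. The hypoxia list was lower at an adjusted p of 0.000984 (adjusted p = 0.131 with an estimated correlation). Of the 5 tested genes of the MondoA glucose-sensing list, ARRDC4 (−0.97 ± 0.09), KLF11 (−0.60 ± 0.07), KLF10 (−0.66 ± 0.09) and MLX (−0.20 ± 0.06) fell and MLXIP, which encodes MondoA, rose (0.31 ± 0.08). The counts of 4 and 1 were equal adjusted over the list alone. With the replicate block 3 fell, and MLX was not past the threshold (adjusted p = 0.0734). MLXIP was not past it when any vehicle library was left out (adjusted p of up to 0.0794). The list test gave an adjusted p of 0.0210 (adjusted p = 0.131 with an estimated correlation).

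DNA replication genes fell: 27 of 34 tested members of the replication and G1/S list were lower and none higher (28 lower adjusted over the list alone). The helicase subunit genes MCM2 (−0.96 ± 0.07) and MCM6 (−0.79 ± 0.05), the flap endonuclease gene FEN1 (−0.93 ± 0.06) and CLSPN (−0.94 ± 0.09) had the smallest p. MCM2 went from 27.9 ± 1.57 to 13.8 ± 0.986 FPKM (adjusted p = 0.000128). The median was −0.50, and the list test gave an adjusted p of 5.24e-15 (adjusted p = 0.0141 with an estimated correlation). Of 30 G2/M and mitosis genes, 15 fell and 1 rose (18 and 2 adjusted over the list alone), by smaller amounts. CCNB1 (−0.32 ± 0.04), BIRC5 (−0.42 ± 0.07) and CDC20 (−0.42 ± 0.07) fell and the kinesin gene KIF2C rose (0.36 ± 0.06). This list was lower at an adjusted p of 0.000622 (adjusted p = 0.176 with an estimated correlation). In the list of p53 targets and arrest genes, 9 of 22 rose and 1, PLK2, fell (12 and 1 adjusted over the list alone). The cell cycle inhibitor gene CDKN1A rose from 57.8 ± 2.00 to 144 ± 5.50 FPKM (1.30 ± 0.05, adjusted p = 3.97e-06), GADD45A by 1.11 ± 0.07, TNFRSF10B by 0.75 ± 0.06 and XPC by 0.63 ± 0.08. The list test gave an adjusted p of 0.00118 (adjusted p = 0.0762 with an estimated correlation).

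**Figure D2:**
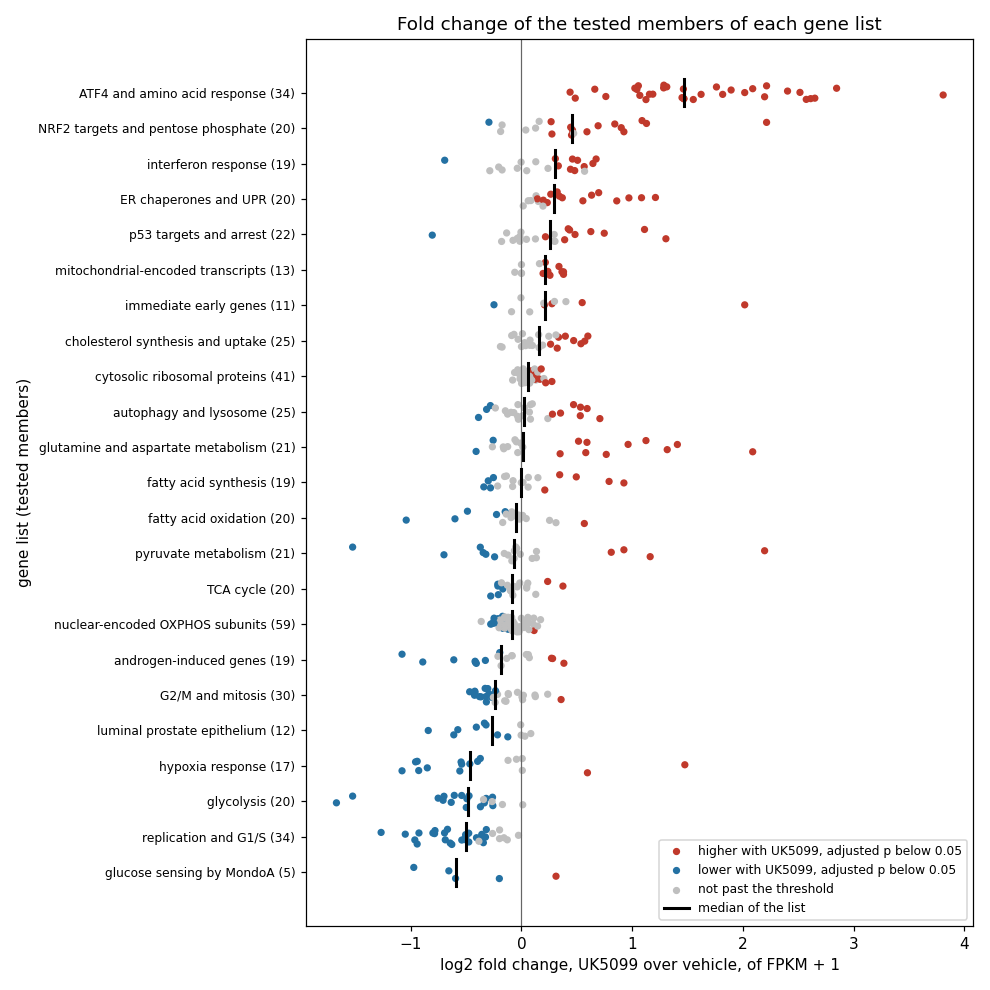
Log2 fold change (UK5099 over vehicle, of FPKM + 1; horizontal axis) of each tested member (points) of the 23 gene lists tested, ordered by median (black bars), with the number of tested members in brackets; red and blue points are higher or lower at an adjusted p below 0.05. All 34 points of the ATF4 list are red, while 16 of 20 glycolysis and 27 of 34 replication points are blue.

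Of 19 androgen-induced genes, 8 fell and 3 (HOMER2, STEAP2 and ZBTB10) rose, the same counts as adjusted over the list alone. With the replicate block 7 fell and 2 rose, and ZBTB10 was not past the threshold (adjusted p = 0.0761). NDRG1, also in the hypoxia list, the prostatic acid phosphatase gene ACPP (−0.89 ± 0.08) and TMPRSS2 (−0.41 ± 0.06) fell. KLK3, which encodes prostate-specific antigen, was not tested: it lay between 0 and 0.149 FPKM in all 6 libraries. The list test gave an adjusted p of 0.0286 (adjusted p = 0.190 with an estimated correlation), and 0.0830 without UK5099 replicate 2 and 0.0733 with the stricter filter (range over the alternatives with camera 0.00828 to 0.190). Of 12 luminal genes, 8 fell and none rose, the same counts as adjusted over the list alone. HOXB13 (−0.84 ± 0.06) and SPDEF (−0.58 ± 0.06), which encode prostate lineage transcription factors, fell, while the keratin gene KRT8 was at 104 ± 2.58 and 105 ± 0.635 FPKM. The luminal list was lower at an adjusted p of 0.00136 (adjusted p = 0.131 with an estimated correlation).

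Genes for glutamine and aspartate metabolism rose in part: 10 of 21 were higher and 2, GOT2 and SLC25A13, were lower, the same counts as adjusted over the list alone. Besides ASNS, the transporter genes SLC1A5 (1.32 ± 0.06) and SLC7A5 (1.12 ± 0.06) and the cytosolic aminotransferase gene GOT1 (0.96 ± 0.05) rose. The list median was 0.01, and the list test gave an adjusted p of 0.00178 (adjusted p = 0.131 with an estimated correlation). In the list of NRF2 targets and pentose phosphate genes, 13 of 20 rose and 1, the glutathione reductase gene GSR, fell (15 and 3 adjusted over the list alone). The cystine transporter gene SLC7A11, which the ATF4 list also holds, rose by 2.21 ± 0.09, SRXN1 by 0.84 ± 0.06 and the ferritin gene FTH1 by 0.59 ± 0.03. This list was higher at an adjusted p of 4.48e-08 (adjusted p = 0.0762 with an estimated correlation).

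Lipid genes went both ways. Cholesterol synthesis and uptake genes rose in 8 of 25 cases and fell in none (9 higher adjusted over the list alone): among them INSIG1 by 0.57 ± 0.06 and HMGCS1 by 0.47 ± 0.07. The list test gave an adjusted p of 0.00239 (adjusted p = 0.0762 with an estimated correlation). Of 19 fatty acid synthesis genes, 5 rose and 4 fell (5 and 6 adjusted over the list alone). ACSL1 (0.50 ± 0.05) and ACACB (0.79 ± 0.10) rose and FADS1 fell (−0.25 ± 0.06). This list did not pass (adjusted p = 0.583), and its median of −0.0016 and mean of 0.06 differed in sign. Of 20 fatty acid oxidation genes, 5 fell and 1, ACADVL (0.57 ± 0.05), rose, the same counts as adjusted over the list alone. CPT1A, which starts the import of fatty acids into mitochondria, fell from 47.9 ± 2.57 to 22.8 ± 2.08 FPKM (−1.04 ± 0.08, adjusted p = 0.000117), ACAA2 by 0.60 ± 0.09 and SLC25A20 by 0.49 ± 0.10. The oxidation list did not pass (adjusted p = 0.134), though it did without a filter on low values (0.0322), over a range of 0.0322 to 0.302.

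Genes of mitochondrial respiration changed little. Of 59 nuclear-encoded subunits of oxidative phosphorylation, 10 fell and 1, COX6A1, rose (10 and 0 adjusted over the list alone). ATP5H (−0.27 ± 0.04), SDHD (−0.28 ± 0.05), ATP5G3 (−0.25 ± 0.05) and ATP5A1 (−0.17 ± 0.03) fell. The list median was −0.09 and its test gave an adjusted p of 0.00749 (adjusted p = 0.302 with an estimated correlation). Of 20 TCA cycle genes, 5 fell, among them IDH2 (−0.21 ± 0.05) and CS (−0.21 ± 0.05), and 2, IDH1 (0.37 ± 0.06) and IDH3B, rose, the same counts as adjusted over the list alone. With the replicate block 3 fell. IDH2 and CS were not past the threshold without UK5099 replicate 1 or any 1 of the vehicle libraries (adjusted p of up to 0.0590 and 0.0817). The TCA list did not pass (adjusted p = 0.258).

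Of the 13 protein-coding transcripts of the mitochondrial genome, 8 were higher with UK5099 and none lower (8 adjusted over the list alone), with a list test at an adjusted p of 1.43e-06 (adjusted p = 0.0348 with an estimated correlation). MT-ND4L was at 22878 FPKM in every UK5099 library and at 17582 in every vehicle library, and MT-CO2 at 15357 and 11916. MT-ND3 was at 6961 and 5504 FPKM, and MT-ND4 at 11916 and 9969. These values lie 1 or 2 ranks apart on the quantile-normalized scale, on which MT-RNR2 held 22878 FPKM in the vehicle libraries and 0 in the others. When the values were ranked again without MT-RNR2, an alternative chosen after seeing the data, 2 members were higher, 2 were lower and the list did not pass (adjusted p = 0.445).

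**Figure D3:**
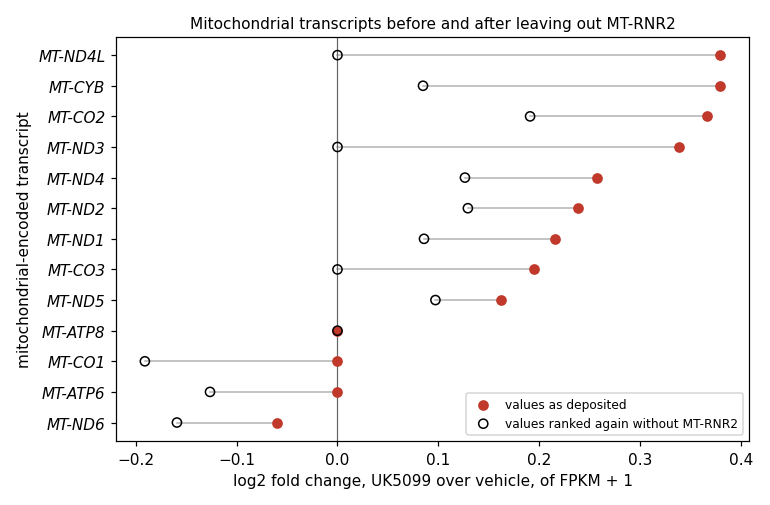
Log2 fold change (UK5099 over vehicle, of FPKM + 1; horizontal axis) of the 13 mitochondrial-encoded protein-coding transcripts, with the values as deposited (filled points) and after leaving out MT-RNR2 and ranking the values of each library again (open points). The value of MT-ND4L moves from 0.38 to 0, and 2 members lie below 0 at an adjusted p under 0.05 after ranking again.

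Of 19 interferon response genes, 9 rose and 1, OAS3 (−0.69 ± 0.10), fell (10 and 2 adjusted over the list alone). IFIT2 (0.67 ± 0.07), IFIT1 (0.48 ± 0.08) and OASL (0.65 ± 0.12) rose, and the list test gave an adjusted p of 0.0107 (adjusted p = 0.109 with an estimated correlation). Of 11 immediate early genes, 4 rose and 1, MYC (−0.25 ± 0.07), fell (6 and 1 adjusted over the list alone). MYC was not past the threshold without UK5099 replicate 1 or 3 or any 1 of the vehicle libraries (adjusted p of up to 0.0968). ATF3, also in the ATF4 list, rose from 11.6 ± 2.17 to 49.5 ± 2.38 FPKM (2.02 ± 0.11), and JUND rose by 0.55 ± 0.11. This list passed at an adjusted p of 0.0193 (adjusted p = 0.287 with an estimated correlation), and not without UK5099 replicate 2 (0.0781) or with the stricter filter (0.0933), over a range of 0.0077 to 0.287. Of 25 autophagy and lysosome genes, 7 rose and 3 fell, the same counts as adjusted over the list alone. The autophagy receptor gene SQSTM1 (0.53 ± 0.05), WIPI1 (0.71 ± 0.07), MAP1LC3B (0.59 ± 0.06) and GABARAPL1 (0.53 ± 0.05) rose. That list did not pass (adjusted p = 0.115), though it did without UK5099 replicate 3 (0.0314), over a range of 0.0314 to 0.517. Of 41 cytosolic ribosomal protein genes, 8 rose and none fell (3 adjusted over the list alone), among them RPLP0 (0.28 ± 0.04), RPS19 (0.22 ± 0.04) and RPL10A (0.17 ± 0.03). The list median was 0.06, with an adjusted p of 0.00132 (adjusted p = 0.0762 with an estimated correlation).

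Markers of other cell types were mostly below the filter, and their lists were too small to test. Of 18 neuroendocrine markers 3 were tested and 1, STMN1 (−0.25 ± 0.08), fell, as adjusted over the list alone. STMN1 was not past the threshold without UK5099 replicate 1 or 2 or any 1 of the vehicle libraries (adjusted p of up to 0.132). Of 10 basal epithelial markers 3 were tested and 1, ITGA6 (0.20 ± 0.06), rose (2 adjusted over the list alone), with an adjusted p of 0.0326, or 0.0526 with the replicate block and up to 0.130 without UK5099 replicate 1 or 3 or any 1 of the vehicle libraries. Of 15 fibroblast and mesenchymal markers 4 were tested. COL1A1 (0.56 ± 0.12) rose, and FN1 (−0.32 ± 0.08) fell at an adjusted p of 0.0272, or 0.0516 with the replicate block and up to 0.0881 without vehicle replicate 1 or 3; 2 rose and 1 fell adjusted over the list alone. Of 12 immune cell markers only CD68 was tested, at 4.61 ± 0.914 and 3.06 ± 0.665 FPKM (0.46 ± 0.15, adjusted p = 0.0579). It was past the threshold with the replicate block (adjusted p = 0.0185). Its p adjusted over the list alone was below 0.05, but with only CD68 tested this is the unadjusted p.

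Of the 23 lists tested by camera, 10 were higher and 8 lower with the preset correlation. With an estimated correlation 4 passed: ATF4 and amino acid response, endoplasmic reticulum stress, replication and G1/S, and mitochondrial-encoded transcripts. The mitochondrial list did not pass by camera with the preset correlation when the values were ranked again without MT-RNR2 (adjusted p = 0.445).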

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

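More lines with low FPKM were above 0 in the UK5099 libraries than in the vehicle libraries, among the 46458 lines that the filter left untested. The numbers were 11870, 12931 and 11722 with UK5099 and 10009, 10077 and 9691 with vehicle, so that the lowest UK5099 library held more than the highest vehicle library. These values were noted because they lie outside the tested genes and above the level of the control libraries. Lines above 0 in all 3 UK5099 libraries and in no vehicle library numbered 339, and 23 lines showed the opposite. The depth of the libraries is unknown, and no explanation was tested.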

How the results depend on the processing

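The ranking without MT-RNR2 and the removal of GC and length trends were chosen after seeing the data; the other alternatives were planned. Of 105 genes named by the rule and past the threshold, 86 kept direction and call under every setting that gave a value, and 19 lost the call under at least 1; none changed direction. Of the 19, IDH2, CS, MLXIP, ZFP36, MYC, RPL37, STMN1, ITGA6 and FN1 lost it with a library left out. Without a filter on low values, which tests more genes, RP11-598P20.5, CTC-535M15.1, HOXA11-AS1_4, MT-ND4, JUND and COL1A1 lost it, without a variance trend ATP5A1 and RPL10A, and with the ranking without MT-RNR2 MT-ND4L and MT-ND3. MT-RNR2, listed at 0 in a whole group, was left out of this comparison. MPC1, near 0, ranged from −0.062 to 0.057 with 1 library left out and turned positive with TMM factors (0.0099), without UK5099 replicate 2 (0.057), without vehicle replicate 2 (0.0096) and with GC and length trends removed (0.0097). The pyruvate list turned with fry (adjusted p = 0.600). fry tests whether a list's genes move, on balance, in a direction, and does not compare them with other genes, so its 21 calls are not set against those of camera. The counts of genes fell to 433 higher and 305 lower with the 1.5-fold threshold, and to 846 and 926 at 0.01, by construction. Leaving out each library in turn gave 1093 to 1572 higher genes, 1298 to 1938 lower genes and 16 to 19 lists; the lowest counts of genes were without UK5099 replicate 1, and the cause was not tested. An estimated correlation left 4 of 18 lists. That test also has fewer degrees of freedom than the preset one, so the losses do not measure correlation alone. How far each contributed was not tested. The estimate was above the preset 0.01 for some lists that lost the call, such as glycolysis (0.364). It was below 0.01 for others, such as p53 targets (−0.0265), interferon response (−0.0495) and MondoA glucose sensing (−0.1175). A higher correlation between genes therefore cannot account for every loss. For p53 targets the unadjusted camera p rose from 0.000461 to 0.01825 although the estimate was below the preset. With the replicate block, 1589 genes were higher, 1916 lower and 18 lists passed, and 1482 higher and 1766 lower genes were called with and without it. The block ended the calls of ZFP36 (adjusted p = 0.0505) and RPL37 (0.0518) and, as given above, of ITGA6, FN1, MLX and ZBTB10, and of no other gene named here and no list. Scaling alternatives moved the median of all genes by less than 0.02 log2 units and the share of higher genes from 45.8% to at most 50.5%. The deposited values already had nearly the same distribution in every library, so further scaling could change little. These alternatives therefore do not test the authors' normalization. The lack of counts leaves unknown how far depth limits the genes with low FPKM.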

Other observations

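The gene groups in this paragraph and the next were chosen after the data were seen, and their tests, adjusted over 6 groups, are descriptive. Other groups looked at in the same way (amino acid transporters, serine synthesis, actin and SRF targets and the mitochondrial unfolded protein response) are not reported. A group of hypoxia-inducible factor targets outside glycolysis was tested and then left out, because its members had been picked with their values known and it lacked VEGFA and P4HA2, which rose. Cytosolic tRNA synthetases, which load amino acids onto tRNA, rose in 11 of 20 cases and fell in 3. SARS rose most (1.70 ± 0.04), followed by GARS (1.62 ± 0.06), while DARS (−0.52 ± 0.07), KARS (−0.31 ± 0.04) and FARSB (−0.24 ± 0.05) fell. Of these 20 genes, 5 are also in the ATF4 list, and among the other 15, 6 rose and 3 fell, with a median of 0.09. Of 17 mitochondrial tRNA synthetases, none rose and 5 fell, with MARS2 at −0.61 ± 0.08. The camera test gave an adjusted p of 6.21e-05 for the cytosolic group (adjusted p = 0.110 with an estimated correlation) and 0.0418 for the mitochondrial group (adjusted p = 0.110 with an estimated correlation). The difference between the groups was not tested. Of 74 tested mitochondrial ribosomal protein genes, 25 fell and 2 rose (median −0.15, adjusted p = 6.21e-05; adjusted p = 0.110 with an estimated correlation).

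Of 5 mitochondrial one-carbon enzymes 4 rose, MTHFD2 (1.82 ± 0.04), SHMT2 (1.16 ± 0.05), MTHFD1L (1.08 ± 0.09) and ALDH1L2 (0.76 ± 0.10), of which 3 are also in the ATF4 list (adjusted p = 6.21e-05; adjusted p = 0.0417 with an estimated correlation). Of 8 cytosolic enzymes 3 fell, among them MTHFD1 (−0.57 ± 0.06) and ATIC (−0.40 ± 0.06), and 1, ALDH1L1 (0.65 ± 0.09), rose (adjusted p = 0.0378; adjusted p = 0.110 with an estimated correlation). The difference between the compartments was not tested, and 2 of the 8 are also in the replication list. Genes of ribosome assembly fell in 17 of 30 cases and rose in 1, GNL3 (0.44 ± 0.08), with a median of −0.26. NOP56 went from 179 ± 11.1 to 98.5 ± 2.41 FPKM (−0.85 ± 0.05). This group was lower at an adjusted p of 6.69e-07 (adjusted p = 0.0229 with an estimated correlation).

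The tests of GC content, of transcript length, of matched random lists, of hypoxia genes in no other list, of shared list members, of folding enzymes and of ranking again were chosen after the results were seen; the count of splits was planned. Over the 10 splits of the 6 libraries into 3 and 3, the real split called 3775 genes and the highest other split 3, and it called 18 lists against 12. In each case 1 split, the real one, reached the count, and 10 splits are too few for a share under 0.05. Among the 4 splits that part all 3 same-numbered pairs, the highest other split called 1 gene and 9 lists. Each of the other splits sets 2 libraries of a treatment and 1 of the other against the rest, so it keeps part of the treatment difference. That difference also adds to the spread within its groups, which holds down its gene calls. Neither its gene calls nor its list calls measure false calls.

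The rise of mitochondrial-encoded transcripts may come from the authors' quantile normalization. MT-RNR2 was listed at 0 in the UK5099 libraries and held rank 2 in the vehicle libraries, which moves transcripts below it up in the UK5099 libraries. Leaving it out and ranking again took the list median from 0.22 to 0 and its adjusted p to 0.445. Whether these transcripts changed by less than the steps between ranks remains open, as does why MT-RNR2 was listed at 0. MT-RNR1, the small ribosomal RNA of the mitochondrial genome, was at 8632 to 9969 FPKM in the UK5099 libraries and at 8632 in the vehicle libraries.

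The fall of glycolysis genes was not explained by GC content or transcript length: with these trends removed the list median was −0.469, against −0.483 before. Genes matched on mean expression did not fall as glycolysis genes did. The medians of 10000 random lists of them centred on −0.00874, and the lowest was −0.276. This argues against compression of abundant genes by the normalization. The random genes were drawn independently, while glycolysis genes vary together (estimated correlation 0.364). The spread of the random lists is therefore too narrow to give a chance level. A candidate explanation is lower activity of hypoxia-inducible factors. The 14 hypoxia genes in no other list had a median of −0.431, with 8 lower and 2 (VEGFA and P4HA2) higher, and a camera p of 0.00658, but 0.184 with an estimated correlation. This therefore remains open.

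The rise of the ATF4 list was likewise left at a median of 1.48 when GC and length trends were removed. The endoplasmic reticulum list shares no tested member with the ATF4 list. A check of its members outside the ATF4 list therefore repeats the list test given above and adds no evidence of its own. The median was 0.294, with an unadjusted camera p of 0.00273 with an estimated correlation. The rise of this list, already reported, argues against a response without endoplasmic reticulum stress genes. For the 12 chaperones and folding enzymes of the list alone this stays open, with a median of 0.196, 6 higher and none lower. Their camera p was 5.87e-06, but 0.0720 with an estimated correlation. Sharing no member with the ATF4 list does not show that the endoplasmic reticulum stress genes rose independently of ATF4. It may thus be that UK5099 at 100 µM raised both amino acid and endoplasmic reticulum stress genes; these data do not say by which route, and 1 dose and 1 inhibitor cannot separate the pyruvate carrier from other targets.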
